A study of Mus musculus with 118 samples.

How the data were processed

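The series measured messenger RNA bound to ribosomes in 3 kinds of neurons of the mouse prefrontal cortex. In the RiboTag method, Cre recombinase switches on an epitope-tagged ribosomal protein in 1 cell type, and the tagged ribosomes are then pulled down with the RNA they carry. The 3 Cre lines were Rbp4, which marks pyramidal neurons of layer 5, Cux2ERT, an inducible line for neurons of the upper layers, and PV, which marks interneurons that make parvalbumin. Mice had received an intraperitoneal injection of 2 mg/kg DOI, a phenethylamine agonist of serotonin 2A and 2C receptors, of 2 mg/kg psilocybin, a tryptamine whose active metabolite psilocin acts on the same receptors, or of saline. Libraries came from 118 samples in 24 groups. The psilocybin set had its own saline groups. By the labels, 53 libraries came from females and 65 from males. The labels also gave a batch: b1 held 12 libraries, b2 72, b3 6 and b4 28. Batch b4 was the whole psilocybin set, so that no difference in level between the sets was read as an effect. The labels did not say that each library came from another animal, so that p-values measure the spread between these samples.

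Per the labels' protocols, libraries were made from 50 ng of poly-A RNA with a stranded TruSeq kit and read as pairs of 150 bp on a NovaSeq for the DOI set and an X Plus for the psilocybin set. Per the submitters' processing notes, the tools used were FastQC 0.11.9, cutadapt 3.5, Trim Galore 0.6.7, STAR 2.7.10a, Bowtie2 2.4.4 and RSEM 1.3.1 with the mouse build GRCm39. The release of the gene annotation and the settings of these tools are not given in the sources used here. Per the file headers, the deposited tables give for each gene an expected count, which RSEM estimates by sharing reads among transcripts, and a mean length of its transcripts in bp weighted by their abundance. Reads that fit near-identical genes are shared by estimate, so that values of paralogs and pseudogenes are less certain. A pair of deposited matrices held the same expected counts. Each table listed 40853 genes by symbol, 19774 with at least 2 transcripts. Positions are not given, because the genome annotation at hand was of another build.

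Expected counts were rounded to whole numbers (88.5% were already whole within 0.005) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Each line was fitted apart, with its 6 DOI-set groups sharing the estimate of the spread and with sex and batch as covariates. The psilocybin set was fitted per line with sex as a covariate. Differences of the DOI effect between times were tested in the same fits, differences between lines in 1 fit of the 90 DOI-set libraries, and differences between compounds in a fit of the 48 h libraries of both sets of a line. The last compared each drug with its own saline group. The lines were compared in the saline libraries of the DOI set, averaged over the times. Values in CPM are scaled by TMM and given as mean ± SD. In 2 cases a covariate took up a whole library, PV DOI 1 month replicate 5 by its batch and Cux2ERT psilocybin replicate 4 by its sex, so that the effective n was 4 and 3 there.

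Gene lists, 32 in number with at least 5 tested members, were fixed before the data were examined and covered synaptic, channel, RNA-processing, metabolic and stress genes and markers of cell types. They were tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and adjustment over 384 tests (32 lists in 12 drug comparisons). Each call was set beside camera with an estimated correlation and beside fry, which tests for a move in one direction and for change in either. The source cells of mitochondrially encoded mRNAs and of markers of other cell types were not tested. Where members of a list were counted, they were also adjusted over the list alone. Scores of cell types were mean log2 CPM with a prior count of 1 and were compared by two-sided exact permutation tests. Transcript length was tested with limma (trended, robust) on log2 of the RSEM length, over genes with at least 2 transcripts and a mean expected count of at least 100. A shift of this mean length does not show which exons were involved, since reads over splice junctions were not analysed here.

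The genes named for each drug comparison were, by a rule fixed before the data were examined, the 8 called genes with the largest rise and the 8 with the largest fall, with a mean of at least 1 CPM and without predicted or clone names, and up to 3 called members of each list. Where fewer than 5 genes were called, the 5 with the smallest p were given as values and not as changes. The rule did not say whether the limits on CPM and name held for these too. They were applied, which passed over genes with smaller p. A few genes that the rule took are not reported here. Htr2a, Fos, Arc, Bdnf, Ntrk2 and Egr1 were given in every drug comparison. For differences between times, lines and compounds the rule took the 5 called genes with the smallest adjusted p. Between lines it took Rbp4, Cux2, Pvalb, Slc17a7, Gad1, Fezf2, Htr2a and the 5 called genes with the largest difference each way at a mean of at least 10 CPM over the saline libraries. For transcript length it took the 5 called genes with the smallest p.

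At 10 CPM or more, the median standard error of a log2 fold change was 0.0651 to 0.0983 in the drug comparisons. Each test was run on data simulated from the means and spread of these libraries, with some genes changed by known amounts. Genes were drawn independently, without sex, batch or replicate structure, so real shares can be lower and excess list calls could not show. In the 12 drug comparisons edgeR recovered 19.4% to 64.2% of genes changed 1.25-fold, 55.2% to 91.0% at 1.5-fold and 69.7% to 98.5% at 2-fold, the last 2 lowest in PV at 1 week. For effects that differed between compounds the shares were 9.92% to 23.8%, 47.0% to 58.8% and 79.8% to 88.4%, and between times or lines 5.97% to 41.0%, 47.9% to 68.7% and 63.6% to 94.1%. No pair of libraries of a group differed by as little as sampling noise, the lowest chi-square per degree of freedom being 10.9.

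Replicate numbers were shared between groups. Same-numbered libraries deviated together in every pair (correlation over 0.1) only for DOI in Rbp4 at 1 week, where the lowest correlation was 0.216 and the mean 0.385. After removal of sex and batch that mean was 0.004. Alternatives fixed in advance were DESeq2 1.42.0 in place of edgeR and its size factors in place of TMM, voom with sample weights, no filter on low counts, no sex or batch term, the sequencing lane in place of the batch, batches apart, all lines in 1 fit, a replicate block, a glial score as covariate, and each replicate left out in turn. Added after the data were seen were 1 surrogate variable (sva 3.50.0), a fit of only the 2 groups compared, the Rbp4 line without b1, the saline lines within b2, the doubted libraries left out, and transcript length between saline lines. Doubted libraries were the one with the largest residual in each per-line fit and a pair that stood apart by sex-linked genes. The pair were PV saline 48 h replicate 1 and Rbp4 saline 48 h replicate 2, labelled male, which held Y-linked genes at 0.518 of the male median with Xist at 0.00958 CPM. Plots were drawn with matplotlib 3.10.9.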

Results

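Ribosome-bound messenger RNA was sequenced from layer 5 pyramidal neurons (Rbp4 line), upper-layer neurons (Cux2ERT line) and parvalbumin interneurons (PV line) of the mouse prefrontal cortex. The design asked how a single dose of DOI had altered these neurons 48 h, 1 week and 1 month later, and how psilocybin had altered them 48 h later. The DOI set held 90 libraries in 18 groups of 5, and the psilocybin set 28 in groups of 5, or 4 in Cux2ERT. Total expected counts per library ran from 55.85 M to 234.7 M, with a median of 98.54 M.

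The saline libraries separated the lines by known markers (n = 15 per line). Pvalb, which encodes parvalbumin, averaged 1150 ± 130 CPM (SD) in PV, 136 ± 19.2 in Cux2ERT and 30.6 ± 7.23 in Rbp4. The GABA-synthesising enzyme Gad1 followed the same order at 4445 ± 323, 394 ± 59.4 and 25.7 ± 4.04 CPM. Slc17a7, the vesicular glutamate transporter of cortical pyramidal neurons, averaged 1207 ± 140 CPM in Rbp4, 818 ± 65.5 in Cux2ERT and 52.2 ± 22.2 in PV. Fezf2, a transcription factor of deep-layer projection neurons, was at 171 ± 19.6 CPM in Rbp4 against 4.23 ± 0.988 in Cux2ERT and 3.21 ± 1.40 in PV. Cux2 was highest in Cux2ERT (183 ± 18.4 CPM, against 57.4 ± 15.5 in Rbp4 and 118.8 ± 8.46 in PV). The gene Rbp4 itself was higher in PV (38.1 ± 9.41 CPM) than in the Rbp4 line (18.4 ± 2.82) or Cux2ERT (12.5 ± 2.55). Htr2a, which encodes the serotonin 2A receptor, averaged 14.8 ± 2.55 CPM in PV, 13.1 ± 3.21 in Rbp4 and 10.4 ± 1.74 in Cux2ERT. Of these, Htr2a passed the edgeR test only between Cux2ERT and PV (log2 difference -0.49, adjusted p = 0.000109), with adjusted p = 0.153 between Rbp4 and Cux2ERT and 0.0996 between Rbp4 and PV.

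**Figure D1:**
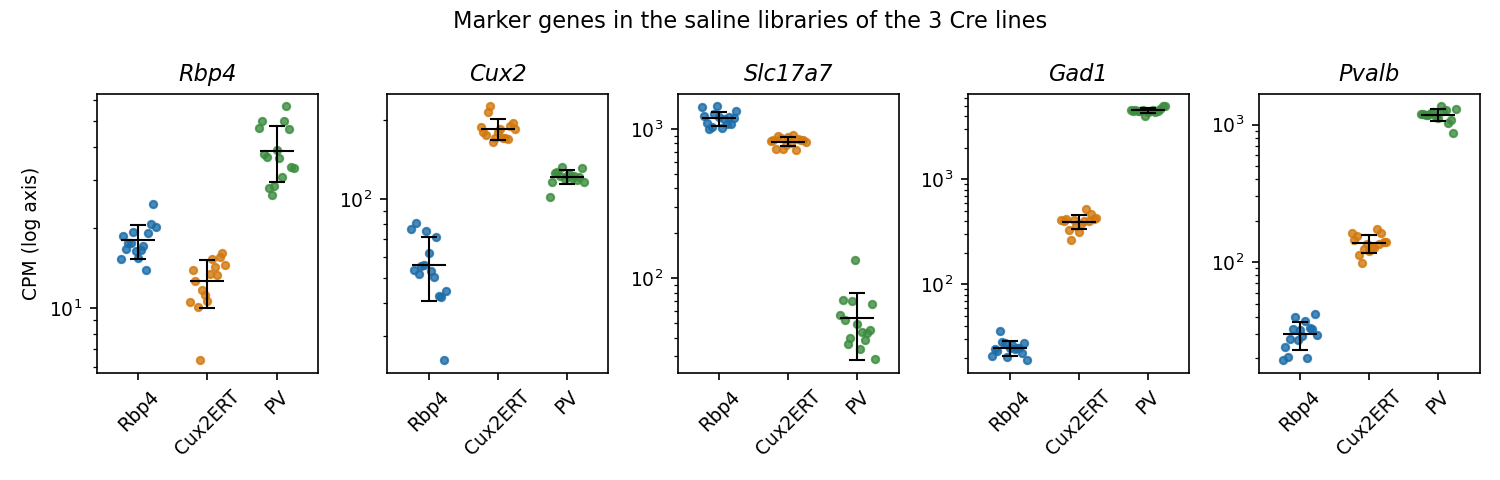
CPM (log axis, not scaled by TMM) of 5 marker genes in the 15 saline libraries of each Cre line in the DOI set; points are libraries, bars the mean ± SD. Slc17a7 lies lowest and Gad1 and Pvalb highest in the PV line, and Cux2 lies highest in the Cux2ERT line.

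Between saline lines, edgeR called 6280 of 19954 genes for Rbp4 against Cux2ERT (3417 higher in Rbp4), 12420 for Rbp4 against PV (7171 higher in Rbp4) and 13176 for Cux2ERT against PV (7214 higher in Cux2ERT). Of these libraries batch b2 held 9 in Rbp4, 13 in Cux2ERT and 15 in PV, b1 only Rbp4 and b3 only Cux2ERT. Within b2 alone 6658, 13330 and 14064 genes were called, and 5938, 12183 and 13108 of the above in the same direction. The largest differences among called genes that averaged at least 10 CPM over the saline libraries of all 3 lines were as follows. Fezf2, S100b (92.3 ± 15.9 against 3.23 ± 1.00 CPM), Pdlim1, Pcp4 and Lratd2 were higher in Rbp4 than in Cux2ERT. The neuropeptide genes Penk (43.4 ± 5.36 against 2.82 ± 1.05 CPM) and Tac1 were higher in Cux2ERT, as were Akr1c18, Mybpc1 and Lrrc38, which averaged at most 8.34 CPM in either of these lines and met that minimum by their level in PV. Tnnc1, Crym, Dkkl1, S100a10 and Pdlim1 stood highest in Rbp4 relative to PV, and S100a6, Wnt10a, Ovol2, Mylk3 and Tuba1c (15.6 ± 19.6 CPM) in Cux2ERT relative to PV. In PV, Akr1c18, Mybpc1, Lrrc38, Tac1 and Pde5a stood highest relative to Rbp4, and Syt2, a calcium sensor of fast transmitter release, Adamtsl5, Bag3, Lrrc38 and Akr1c18 relative to Cux2ERT.

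The fixed lists of cell-type markers followed the lines, with member counts from the edgeR calls over all genes. Layer 5 markers were higher in Rbp4 than in Cux2ERT for 19 of 24 genes (median log2 difference 2.16), and layer 2/3 markers were lower for 16 of 22 (median -0.95). All 15 pan-excitatory markers were higher in Rbp4 and in Cux2ERT than in PV (medians 4.46 and 4.42). Parvalbumin interneuron markers were lower in Rbp4 than in PV for 26 of 28 genes (median -5.31), in Cux2ERT than in PV for 25 (median -3.03), and in Rbp4 than in Cux2ERT for 21 (median -2.57). Cux2ERT libraries also held more of the oligodendrocyte markers than Rbp4 libraries (17 of 22 genes, median -1.34 for Rbp4 minus Cux2ERT). Immediate early genes, induced by neuronal activity, were lower in PV for 25 of 29 genes against either other line (medians 2.66 and 2.88). Nuclear genes of oxidative phosphorylation were highest in PV: 70 of 75 were lower in Cux2ERT than in PV (median -0.65) and 50 were lower in Rbp4 (median -0.31). Cholesterol synthesis genes were higher in Rbp4 than in PV for 22 of 24 genes (median 1.3) and than in Cux2ERT for 21 (median 0.57).

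In Rbp4 libraries 48 h after DOI, lists of channels, glutamate receptors, GABA genes, mitochondrial mRNAs and endothelial and astrocyte markers lay slightly lower than in saline, and immediate early genes and ribosomal proteins slightly higher. Of 40 voltage-gated channels 36 were lower (median log2 fold change -0.06, camera adjusted p = 1.57e-09), as were 23 of 27 glutamate receptors (median -0.05, adjusted p = 6.66e-06), both 0.720 with an estimated correlation. Genes of GABA synthesis, transport and receptors were lower for 19 of 21 (median -0.07, adjusted p = 3.44e-07, and 0.642 with an estimated correlation). The 13 mitochondrially encoded mRNAs were all lower (median -0.22, adjusted p = 0.000541) and the immediate early genes higher for 22 of 29 (median 0.04, adjusted p = 0.00208), both 0.856 with an estimated correlation. Cytosolic ribosomal proteins were higher for 67 of 79 (median 0.04, adjusted p = 7.07e-07, and 0.948 with an estimated correlation). Endothelial and mural markers were lower for 13 of 15 (median -0.16, adjusted p = 0.00363) and astrocyte markers for 19 of 22 (median -0.135, adjusted p = 0.0481), at 0.642 and 0.913 with an estimated correlation. Parvalbumin interneuron markers (20 of 27 lower, median -0.08, adjusted p = 0.084) and oligodendrocyte markers (18 of 22 lower, median -0.11, adjusted p = 0.0958) were not called. The marker scores of these cell types differed by -0.143, -0.127, -0.086 and -0.121 (two-sided exact permutation p of at least 0.341, n = 5 and 5). No member of these lists passed when adjusted over the list alone. Of 32 lists 15 were called, 4 higher and 11 lower, with 7 in all without DOI replicate 1 and 8 without saline replicate 4. Without DOI replicate 1 the calls of channels (adjusted p = 0.167), glutamate receptors (0.355) and endothelial markers (0.0983) ended, and without saline replicate 4 those of mitochondrial mRNAs (0.507) and layer 2/3 markers (0.909). Ribosomal proteins were not called without DOI replicate 2 or saline replicate 1 or 4 (0.0654 to 0.887), immediate early genes without DOI replicate 2 (0.543) or saline replicate 3 (0.923, direction turned), and endothelial markers without saline replicate 1 or 5 (0.0543 and 0.0568). Astrocyte markers were not called without DOI replicate 4 or 5 or saline replicate 1, 3 or 4 (0.0755 to 0.763). No single gene was called among 18692 by edgeR, 12 had an unadjusted p under 0.05 where chance gives 935, and DESeq2 and voom called 0, against 14 with no filter on low counts. Among genes with an established name and a mean of at least 1 CPM, the 5 with the smallest p were Tfrc, the transferrin receptor (log2 fold change -0.28 ± 0.11 SE), Rtn4, Exosc9, Acyp2 and Rps4l, each at an adjusted p of 1. Fos (0.03 ± 0.18), Egr1 (0.01 ± 0.15), Arc (0.04 ± 0.20), Bdnf (-0.01 ± 0.16), Ntrk2 (-0.05 ± 0.07) and Htr2a (-0.05 ± 0.23) differed by less than their standard errors.

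At 1 week after DOI, the only list called in Rbp4 was that of mitochondrially encoded mRNAs, lower for 13 of 13 (median -0.30, camera adjusted p = 0.0178, and 0.948 with an estimated correlation, 0 adjusted over the list alone). That call ended without DOI replicate 1 or saline replicate 1 or 2 (0.128 to 0.271). The number of lists was 0 without saline replicate 1, 2 without DOI replicate 2 or saline replicate 4 or 5, and 3 without DOI replicate 3. The named genes of at least 1 CPM with the smallest p were Sft2d2 (log2 fold change -1.05 ± 0.27), Ccdc167 (0.62 ± 0.16), the methionine aminopeptidase Metap1 (0.29 ± 0.08), Smim20 (-0.47 ± 0.12) and Fbrs (-0.25 ± 0.07), each at an adjusted p of 0.374. Htr2a was at 0.36 ± 0.23, Fos at -0.22 ± 0.18, Bdnf at -0.25 ± 0.16, Arc at -0.09 ± 0.20, Egr1 at -0.03 ± 0.15 and Ntrk2 at 0.02 ± 0.07. By edgeR 0 genes were called, with 1436 at an unadjusted p under 0.05 (935 by chance, a median of 1760 over other splits of the labels). Within b1 or b2 alone edgeR also called 0, voom called 0 and DESeq2 182 (91 higher, 91 lower). With all lines in 1 fit the count was 85, and with no filter on low counts 80.

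At 1 month, Rbp4 neurons had postsynaptic density scaffolds higher for 27 of 30 genes (median 0.08, camera adjusted p = 3.44e-05, and 0.642 with an estimated correlation). Chromatin modifiers were higher for 38 of 45 (median 0.08, adjusted p = 0.00033, and 0.727 with an estimated correlation). Ribosomal proteins were lower for 71 of 79 (median -0.07, adjusted p = 2.73e-08), nuclear oxidative phosphorylation genes for 60 of 75 (median -0.08, adjusted p = 2.08e-05) and immediate early genes for 24 of 29 (median -0.16, adjusted p = 0.00201). With an estimated correlation these adjusted p were 0.948, 0.948 and 0.856. Oxidative phosphorylation was not called without DOI replicate 2 or saline replicate 5 (0.746 and 0.0573), nor immediate early genes without DOI replicate 3 (0.22). Adjusted over the list alone, 1 gene of the called lists passed, the succinate dehydrogenase subunit Sdhb (log2 fold change -0.27 ± 0.06, 171 ± 25.9 against 203 ± 17.7 CPM). Over all genes Sdhb had an adjusted p of 0.239, as did Acp1 (-0.60 ± 0.12), Tpp2 (0.31 ± 0.07) and Gpr26 (0.46 ± 0.11), which were among the named genes with the smallest p. Fos was at 53.8 ± 14.1 against 76.8 ± 12.4 CPM (-0.48 ± 0.18, adjusted p = 0.488), Egr1 at -0.30 ± 0.15, Arc at -0.31 ± 0.21, Bdnf at -0.13 ± 0.16, and Htr2a and Ntrk2 both at -0.03. Called lists numbered 6, and the call of oligodendrocyte markers (median -0.01, mean -0.14) had 11 members each way (adjusted p = 0.03, and 0.948 with an estimated correlation). It was lost without DOI replicate 3 or 5 or saline replicate 4 (0.152 to 0.985). Called genes numbered 0 by edgeR (1604 at an unadjusted p under 0.05, 935 by chance and a median of 1513 over other splits), 0 by voom and 125 by DESeq2. EdgeR also called 0 within b1 or b2 alone, 46 with all lines in 1 fit, 124 with no filter on low counts, 13 without DOI replicate 5 and 4 without saline replicate 4.

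Upper-layer Cux2ERT neurons 48 h after DOI had ribosomal proteins higher for 74 of 79 genes (median 0.08, camera adjusted p = 1.15e-11, and 0.856 with an estimated correlation). Cholesterol synthesis genes were higher for 23 of 24 (median 0.10, adjusted p = 0.00111, and 0.727 with an estimated correlation). Splicing factors lay higher as well: SR proteins and core spliceosome genes for 47 of 56 (median 0.04, adjusted p = 0.00208) and hnRNPs and neuronal splicing regulators for 42 of 59 (median 0.05, adjusted p = 0.00826). With an estimated correlation these adjusted p were 0.834 and 0.856. Immediate early genes were lower for 25 of 29 (median -0.10, adjusted p = 0.00581, and 0.876 with an estimated correlation). Markers of 3 other cell types were lower: oligodendrocyte markers for 21 of 22 (median -0.21, adjusted p = 8.22e-09), their precursors' for 9 of 14 (median -0.23, adjusted p = 0.0154) and parvalbumin interneuron markers for 23 of 28 (median -0.09, adjusted p = 4.69e-06), each 0.720 with an estimated correlation. Their scores had exact permutation p of at least 0.198. Endothelial and mural markers lay the other way, with a score higher by 0.289 (exact permutation p = 0.0317, n = 5 and 5). Over 96 scores its adjusted p was 0.609, and that list was not called (12 of 19 higher, median 0.05, adjusted p = 0.459). No member of the called lists passed when adjusted over its list alone, 11 lists were called, and the count was 7 without DOI replicate 2. Without that library the calls of cholesterol synthesis (adjusted p = 0.36), hnRNPs (0.218), SR proteins (0.0865), precursor markers (0.256) and immediate early genes (0.0517) ended. Cholesterol synthesis was also not called without saline replicate 1 (0.0601), precursor markers without saline replicate 2 (0.204), hnRNPs without DOI replicate 1 or saline replicate 5 (0.217 and 0.0609), and immediate early genes without DOI replicate 5 or saline replicate 3 (0.0564 and 0.0535). EdgeR called 0 of 18571 genes, with 822 at an unadjusted p under 0.05 against 929 by chance, DESeq2 and voom called 0, and the count was 2 with no filter on low counts. Zcchc7 (0.36 ± 0.09), the GABA transaminase Abat (-0.20 ± 0.05), Eml2 (-0.19 ± 0.05), Myh7 (-0.29 ± 0.08) and Smarcd3 (-0.15 ± 0.04) had the smallest p among named genes, at an adjusted p of 0.999. Changes of Fos (-0.13 ± 0.25), Arc (-0.02 ± 0.25), Egr1 (-0.06 ± 0.12), Bdnf (0.08 ± 0.11), Ntrk2 (-0.02 ± 0.09) and Htr2a (-0.03 ± 0.13) lay within their standard errors.

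By 1 week in Cux2ERT the oligodendrocyte, precursor and parvalbumin interneuron markers, lower at 48 h, lay higher than in saline. Oligodendrocyte markers were higher for 20 of 22 (median 0.18, camera adjusted p = 7.99e-05, and 0.871 with an estimated correlation). Astrocyte markers were higher for 18 of 22 (median 0.12, adjusted p = 0.00267, and 0.748 with an estimated correlation). Parvalbumin interneuron markers were higher for 23 of 28 (median 0.09, adjusted p = 0.00023) and precursor markers for 10 of 14 (median 0.23, adjusted p = 0.0349), both 0.727 with an estimated correlation. The precursor marker Sox10, a transcription factor, was the 1 member of the called lists that passed when adjusted over its list alone. HnRNPs and neuronal splicing regulators were higher for 49 of 59 (median 0.04, adjusted p = 4.86e-05, and 0.720 with an estimated correlation). Voltage-gated channels were lower for 32 of 40 (median -0.07, adjusted p = 0.00172) and mitochondrially encoded mRNAs higher for 11 of 13 (median 0.11, adjusted p = 0.00917), both 0.948 with an estimated correlation. The latter were not called without DOI replicate 2 or 4 or saline replicate 4 or 5 (0.0677 to 0.586). In all 8 lists were called, and 4 with a glial score as covariate. Channels were not called without DOI replicate 1 or saline replicate 3 (0.276 and 0.0578), nor precursor markers without DOI replicate 1, 3 or 4 or saline replicate 5 (0.0623 to 0.157). Among named genes the smallest p belonged to Foxo6, a forkhead factor (6.23 ± 0.828 against 3.82 ± 0.245 CPM, log2 fold change 0.70 ± 0.15) and Prr18 (0.53 ± 0.11), both at an adjusted p of 0.547, and to Lnpk (-0.25 ± 0.06), Mtss2 (0.31 ± 0.08) and N4bp3 (0.38 ± 0.10) at 0.915. Egr1 was at 0.15 ± 0.12, Fos at 0.10 ± 0.25, Arc at 0.05 ± 0.25, Bdnf at 0.03 ± 0.11, Ntrk2 at -0.09 ± 0.09 and Htr2a at -0.08 ± 0.13. Called genes numbered 0 by edgeR (909 at an unadjusted p under 0.05 against 929 by chance), 0 by voom, 3 by DESeq2, 1 when only the 2 groups were fitted and 8 with no filter on low counts.

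One month after DOI, cytosolic ribosomal proteins were higher in Cux2ERT for 77 of 79 genes, by a median of 0.15 (camera adjusted p = 5.98e-37, and 0.642 with an estimated correlation), and 53 of them passed when adjusted over the list alone, none over all genes. Nuclear oxidative phosphorylation genes were higher for 66 of 75 (median 0.08, adjusted p = 5.65e-10, and 0.856 with an estimated correlation), while the 13 mitochondrially encoded mRNAs were all lower (median -0.39, adjusted p = 0.0014, and 0.944 with an estimated correlation). Genes of GABA synthesis, transport and receptors were lower for 17 of 21 (median -0.09, adjusted p = 0.00172, and 0.806 with an estimated correlation), and the GABA-synthesising enzyme Gad2 passed when adjusted over that list alone. Beside them, parvalbumin interneuron markers were lower for 20 of 28 (median -0.08, adjusted p = 0.0886), with a marker score that differed by -0.091 (two-sided exact permutation p = 0.492, n = 5 and 5). Other interneuron markers were lower for 13 of 22 (median -0.02, mean 0.01, adjusted p = 0.593). With 1 library left out at a time both marker lists lay lower in all 10 runs, and the parvalbumin list was called in 4. The GABA list was not called without DOI replicate 1 or saline replicate 4 (0.19 and 0.0736), nor mitochondrial mRNAs without saline replicate 1 (0.0525). Immediate early genes lay higher for 22 of 29 (median 0.12, adjusted p = 0.0306) and heat shock genes lower for 21 of 32 (median -0.05, adjusted p = 0.0246), with adjusted p of 0.948 and 0.876 for an estimated correlation. The first call ended without DOI replicate 1, 2 or 5 or saline replicate 1 or 2 (0.119 to 0.619), and the latter without DOI replicate 3 or 4 or saline replicate 4 or 5 (0.092 to 0.491). Called lists numbered 6, and 12 without DOI replicate 2. EdgeR called 0 genes, with 1634 at an unadjusted p under 0.05 against 929 by chance and a smallest adjusted p of 0.0548, that of the predicted gene Gm13778 (log2 fold change 0.81). Within b2 alone it called 145 (39 lower) and within b3 alone 3, DESeq2 called 2, voom 0, and leaving out DOI replicate 5 or saline replicate 2 gave 6 or 1. The count was 52 with no filter on low counts and 1 each with DESeq2 size factors and with a surrogate variable. Of the named genes Tmem160 had the smallest p (0.39 ± 0.08, adjusted p = 0.259), followed at 0.355 by Fbll1 (0.27 ± 0.06), Lrrc73 (0.26 ± 0.06), Abhd8 (0.19 ± 0.05) and Sap30l (0.38 ± 0.09). Values for Egr1 (0.18 ± 0.12), Bdnf (0.09 ± 0.11), Arc (0.04 ± 0.26), Fos (-0.09 ± 0.25), Ntrk2 (-0.04 ± 0.09) and Htr2a (-0.12 ± 0.13) did not pass.

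Parvalbumin interneurons 48 h after DOI had nuclear oxidative phosphorylation genes higher for 70 of 75 (median 0.15, camera adjusted p = 1.96e-18) and ribosomal proteins for 64 of 79 (median 0.07, adjusted p = 0.00298), at 0.748 and 0.962 with an estimated correlation. Immediate early genes were lower for 18 of 29 (median -0.12, adjusted p = 0.0457, and 0.944 with an estimated correlation), and Fos passed when adjusted over the list alone. The call held in 5 of 10 runs with 1 library left out and ended without DOI replicate 1, 3 or 4 or saline replicate 2 or 4 (0.0848 to 0.434). Pan-excitatory markers were lower for 13 of 15 (median -0.12, adjusted p = 0.323) and lay lower in all 10 runs. In saline replicate 4 Arc was at 36.5 CPM against a median of 14.6 in the other saline libraries, and Slc17a7 at 66.9 CPM (not scaled by TMM) against 29.0 to 44.8. Fos averaged 5.94 ± 1.90 CPM after DOI and 11.2 ± 4.45 after saline (log2 fold change -0.92 ± 0.26, adjusted p = 0.636 over all genes, n = 5 and 5). Egr1 averaged 24.5 ± 4.74 against 36.1 ± 8.58 (-0.55 ± 0.18, adjusted p = 0.636). Axon guidance genes were lower for 35 of 46 (median -0.13, adjusted p = 0.000329, and 0.720 with an estimated correlation). Prpsap1 (0.41 ± 0.09), Ndst3 (-0.43 ± 0.10), the GABA receptor subunit gene Gabra2 (4.82 ± 0.481 against 9.23 ± 2.71 CPM, -0.94 ± 0.23), Tent5a (-0.96 ± 0.24) and Flywch2 (0.48 ± 0.12) had the smallest p among named genes, at an adjusted p of 0.636. Arc (-0.30 ± 0.34), Bdnf (-0.50 ± 0.39), Ntrk2 (-0.05 ± 0.07) and Htr2a (0.02 ± 0.17) did not pass. Ribosomal proteins were not called without DOI replicate 1 or 2 or saline replicate 4 (0.0983 to 0.676), with the direction turned in the last (0.132). The count of 4 lists was 7 without DOI replicate 5 or saline replicate 1, 8 without the doubted libraries and 7 with a replicate block. EdgeR called 0 of 18813 genes (1266 at an unadjusted p under 0.05 against 941 by chance), voom 0 and DESeq2 19 (11 higher), with 54 for all lines in 1 fit and 140 with no filter on low counts.

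After 1 week the ribosomal proteins of PV neurons were higher for 78 of 79 genes (median 0.18, camera adjusted p = 1.29e-18) and nuclear oxidative phosphorylation genes for 72 of 75 (median 0.12, adjusted p = 1.02e-13), at 0.843 and 0.856 with an estimated correlation. Voltage-gated channels were lower for 34 of 40 (median -0.13, adjusted p = 0.000261, and 0.727 with an estimated correlation). Perineuronal net and matrix genes were lower for 19 of 24 (median -0.23, adjusted p = 0.00109) and axon guidance genes for 40 of 46 (median -0.11, adjusted p = 0.000278), at 0.642 and 0.720 with an estimated correlation. No member of the 9 called lists passed when adjusted over its list alone. The smallest p among named genes belonged to the splicing factor Sf3b1 (-0.57 ± 0.13), the natriuretic peptide receptor gene Npr2 (-0.73 ± 0.16), the DNA-dependent protein kinase gene Prkdc (-1.26 ± 0.30), Ankrd16 (-0.84 ± 0.20) and the nucleoporin gene Nup153 (-0.35 ± 0.08), each at an adjusted p of 0.522. Fos (0.49 ± 0.26), Egr1 (0.29 ± 0.18), Bdnf (0.15 ± 0.39), Arc (-0.03 ± 0.34), Ntrk2 (-0.04 ± 0.07) and Htr2a (-0.26 ± 0.17) did not pass. Called genes numbered 0 by edgeR (1397 at an unadjusted p under 0.05 against 941 by chance), 0 by voom and 3 by DESeq2, but 69 without saline replicate 4, 197 with all lines in 1 fit (185 lower) and 312 with no filter on low counts.

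At 1 month in PV, oligodendrocyte markers were lower for 20 of 22 (median -0.24, camera adjusted p = 0.00284, and 0.876 with an estimated correlation, 0 adjusted over the list alone). The call ended without DOI replicate 3 or 4 (0.0883 and 0.0819). This was the 1 list called, and the count was 2 to 5 without any 1 of DOI replicates 1 to 5 or saline replicates 1 to 3, 4 with a replicate block and 2 without the doubted libraries or with DESeq2 size factors. Iars, an isoleucyl-tRNA synthetase gene (-0.59 ± 0.13), Zfp119a (-0.92 ± 0.22), Zbtb8a (-0.79 ± 0.19) and Rrp8 (0.42 ± 0.11) were among the named genes with the smallest p, at an adjusted p of 0.680. Egr1 (0.10 ± 0.19), Arc (0.09 ± 0.35), Ntrk2 (0.07 ± 0.08), Htr2a (0.05 ± 0.18), Fos (0.03 ± 0.28) and Bdnf (-0.05 ± 0.41) lay within their standard errors. EdgeR called 0 genes (1025 at an unadjusted p under 0.05 against 941 by chance), voom 1, DESeq2 7, all lines in 1 fit 9, and about 1.1e+02 were called with no filter on low counts.

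**Figure D2:**
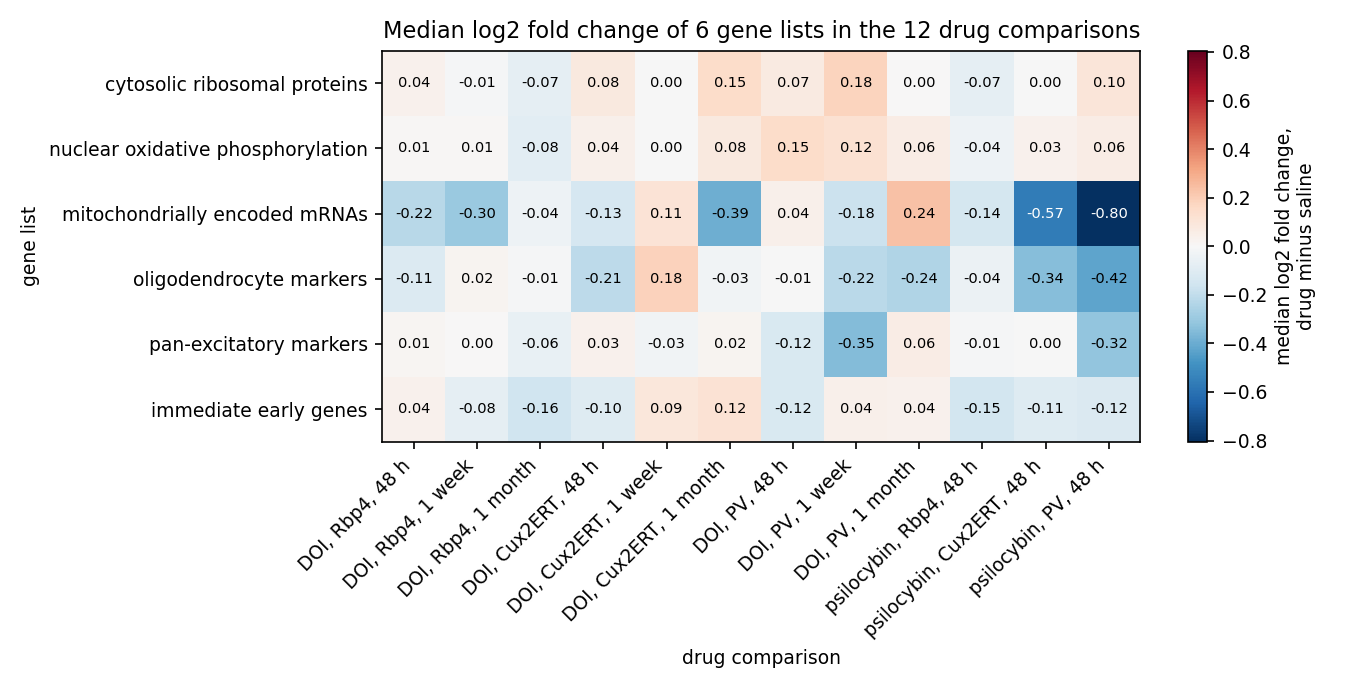
Median log2 fold change (drug minus saline) of the members of 6 gene lists (vertical axis) in each of the 12 drug comparisons (horizontal axis); color and printed number give the median. Mitochondrially encoded mRNAs have the lowest median, -0.80, in PV after psilocybin.

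Psilocybin in Rbp4 neurons left ribosomal proteins lower after 48 h for 75 of 79 genes (median -0.07, camera adjusted p = 1.51e-10) and immediate early genes for 25 of 29 (median -0.15, adjusted p = 0.0108), both 0.948 with an estimated correlation. Mitochondrially encoded mRNAs were lower for 13 of 13 (median -0.14, adjusted p = 0.000366, and 0.876 with an estimated correlation). Heat shock and folding genes were lower for 25 of 31 (median -0.05, adjusted p = 0.00298) and layer 5 markers higher for 16 of 24 (median 0.07, adjusted p = 0.0091), both 0.727 with an estimated correlation. Markers of vascular cells were higher for 13 of 14 (median 0.16, adjusted p = 0.00488, and 0.720 with an estimated correlation) and those of oligodendrocytes lower for 14 of 22 (median -0.045, adjusted p = 0.026, and 0.856 with an estimated correlation). No member passed when adjusted over its list alone. Called lists numbered 14, but 4 with a glial score as covariate, 7 without psilocybin replicate 2, 8 without saline replicate 2 or 4, and 5 without saline replicate 3. The call of immediate early genes ended without psilocybin replicate 3 (0.753) or saline replicate 1 or 2 (0.999 and 0.942, direction turned), that of ribosomal proteins without saline replicate 3 (0.149) and that of mitochondrial mRNAs without psilocybin replicate 5 or saline replicate 3 (0.0552 and 0.203). Heat shock genes were not called without psilocybin replicate 2 or saline replicate 1 (0.0739 and 0.447), layer 5 markers without psilocybin replicate 5 or saline replicate 2 or 3 (0.0945 to 0.327), vascular markers without psilocybin replicate 2 or saline replicate 1 or 4 (0.0876 to 0.1), and oligodendrocyte markers without psilocybin replicate 1, 2 or 4 or saline replicate 1, 3 or 4 (0.0862 to 0.367). Wdfy1 (23.4 ± 14.1 against 7.73 ± 0.695 CPM, 1.5 ± 0.35), Snhg11 (0.34 ± 0.09), B3gat2 (0.46 ± 0.13), Slc1a4 (0.22 ± 0.06) and Ttr had the smallest p among named genes, at an adjusted p of 1. Ttr, abundant in choroid plexus, reached 9.30 CPM in saline replicate 1 against a median of 0.101 in the other saline libraries. Arc (-0.41 ± 0.31), Egr1 (-0.23 ± 0.20), Fos (-0.19 ± 0.37), Bdnf (-0.15 ± 0.11), Htr2a (0.02 ± 0.10) and Ntrk2 (0.01 ± 0.07) did not pass. EdgeR called 0 of 17556 genes (300 at an unadjusted p under 0.05 against 878 by chance), DESeq2 and voom 0, and 46 were called with no filter on low counts.

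In Cux2ERT libraries psilocybin went with lower mitochondrially encoded mRNAs (13 of 13, median -0.57, camera adjusted p = 3.17e-10) and oligodendrocyte markers (22 of 22, median -0.34, adjusted p = 2.46e-10), at 0.727 and 0.748 with an estimated correlation. Astrocyte markers were lower for 17 of 22 (median -0.29, adjusted p = 0.000225) and endothelial and mural markers higher for 12 of 20 (median 0.07, adjusted p = 0.0255). Immediate early genes were lower for 26 of 29 (median -0.11, adjusted p = 0.00694), each of these 3 lists at 0.948 with an estimated correlation. These fits rest on 3 psilocybin libraries, since the sex term took up replicate 4. Over all 4 and 4 libraries the scores differed by -0.148 for oligodendrocyte (exact permutation p = 0.486), -0.086 for astrocyte (0.714) and 0.6 for endothelial and mural markers (0.429). The endothelial call ended without psilocybin replicate 2 or saline replicate 1 or 2 (0.452 to 0.921). Aldoc, a glycolytic enzyme of astrocytes, passed when adjusted over the astrocyte list alone (48.9 ± 6.01 against 61.8 ± 2.86 CPM, -0.42 ± 0.06, adjusted p = 0.535 over all genes, n = 4 and 4). HnRNPs and splicing regulators were higher for 42 of 59 (median 0.03, adjusted p = 0.0109, and 0.720 with an estimated correlation). Called lists numbered 9. The call of immediate early genes ended without psilocybin replicate 1 or saline replicate 2 (0.172 and 0.776), that of astrocyte markers without psilocybin replicate 1 or saline replicate 4 (0.0616 and 0.397), and that of hnRNPs without psilocybin replicate 3 or saline replicate 3 (0.0942 and 0.0975). After Aldoc the smallest p among named genes belonged to Kank1 (-0.81 ± 0.18), Bmp3 (0.37 ± 0.10), Tnfrsf12a (-0.67 ± 0.17) and Cep250 (-0.29 ± 0.08), at an adjusted p of 1. Arc (-0.23 ± 0.14), Fos (-0.17 ± 0.16), Egr1 (-0.11 ± 0.11), Bdnf (0.18 ± 0.11), Ntrk2 (0.08 ± 0.06) and Htr2a (0.02 ± 0.14) did not pass. Fos averaged 85.3 ± 23.9 against 83.1 ± 20.7 CPM over all 4 and 4 libraries, and with no sex term its fold change was 0.04. EdgeR called 0 of 17762 genes (377 at an unadjusted p under 0.05 against 888 by chance), voom 0 and DESeq2 2, both lower.

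PV libraries after psilocybin had the lowest list median of the 12 drug comparisons: the 13 mitochondrially encoded mRNAs were lower by a median of -0.80 (camera adjusted p = 7.58e-27, and 0.642 with an estimated correlation), and all 13 passed when adjusted over the list alone. Whether these mRNAs came from the tagged neurons was not tested. Oligodendrocyte markers were lower for 22 of 22 (median -0.42, adjusted p = 3.27e-20, and 0.444 with an estimated correlation), 9 of them when adjusted over the list alone, among them the myelin genes Mag, Mog and Cnp. Pan-excitatory markers were lower for 14 of 15 (median -0.32, adjusted p = 4.46e-12, and 0.231 with an estimated correlation), 9 of them adjusted over the list alone, Slc17a7, Neurod6 and Tbr1 included. Astrocyte markers were lower for 20 of 21 (median -0.34, adjusted p = 1.54e-09) and immediate early genes for 19 of 29 (median -0.12, adjusted p = 0.000153), both 0.642 with an estimated correlation. Of the latter Arc, Egr1, Egr3 and Npas4 passed when adjusted over the list alone. Egr1 averaged 21.3 ± 4.19 CPM against 34.1 ± 5.32 in saline (log2 fold change -0.62 ± 0.15, adjusted p = 0.571 over all genes, n = 5 and 5). Arc averaged 11.1 ± 2.02 against 18.4 ± 5.30 (-0.68 ± 0.20, adjusted p = 0.818) and Fos 6.18 ± 1.38 against 9.57 ± 2.03 (-0.50 ± 0.18, adjusted p = 0.999). Beside them, marker scores were lower for excitatory neurons by -0.26 (exact permutation p = 0.0159), oligodendrocytes by -0.36 (0.0238), microglia by -0.43 (0.0159) and oligodendrocyte precursors by -0.22 (0.0159), and none passed over 96 such scores (adjusted p at least 0.509).

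Ribosomal proteins in the same PV libraries were higher for 77 of 79 (median 0.10, camera adjusted p = 2.19e-13, and 0.934 with an estimated correlation). Parvalbumin interneuron markers were higher for 21 of 27 (median 0.07, adjusted p = 0.00208, and 0.720 with an estimated correlation), a call lost without saline replicate 5 (0.25), and their score differed by 0.011 (exact permutation p = 0.762). In all 12 lists were called, 3 higher and 9 lower. Transferrin, Trf, had the smallest p among named genes (5.90 ± 0.650 against 8.69 ± 1.75 CPM, -0.74 ± 0.11, adjusted p = 0.112), followed by Arpp21 (-0.54 ± 0.08, 0.121), Gprin3 (-1.11 ± 0.21, 0.356), Rgs14 (-0.92 ± 0.18, 0.398) and Six3. Six3, a homeobox gene, stood at 28.6 CPM in saline replicate 5 against a median of 0.291 in the others. Ntrk2 (0.08 ± 0.06), Bdnf (-0.01 ± 0.32) and Htr2a (-0.10 ± 0.10) did not pass. All 5 psilocybin libraries were from males and 2 of the saline libraries from females, so that with sex in the fit the effect rested on 5 and 3 males. EdgeR called 0 of 16447 genes (751 at an unadjusted p under 0.05 against 822 by chance), voom 0 and DESeq2 21, all lower. EdgeR called 22 without psilocybin replicate 1, 3 without saline replicate 5, 7 with a surrogate variable, 14 with all lines in 1 fit and 41 with no filter on low counts. All of these were lower except 1 of the 3 genes called without saline replicate 5.

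**Figure D3:**
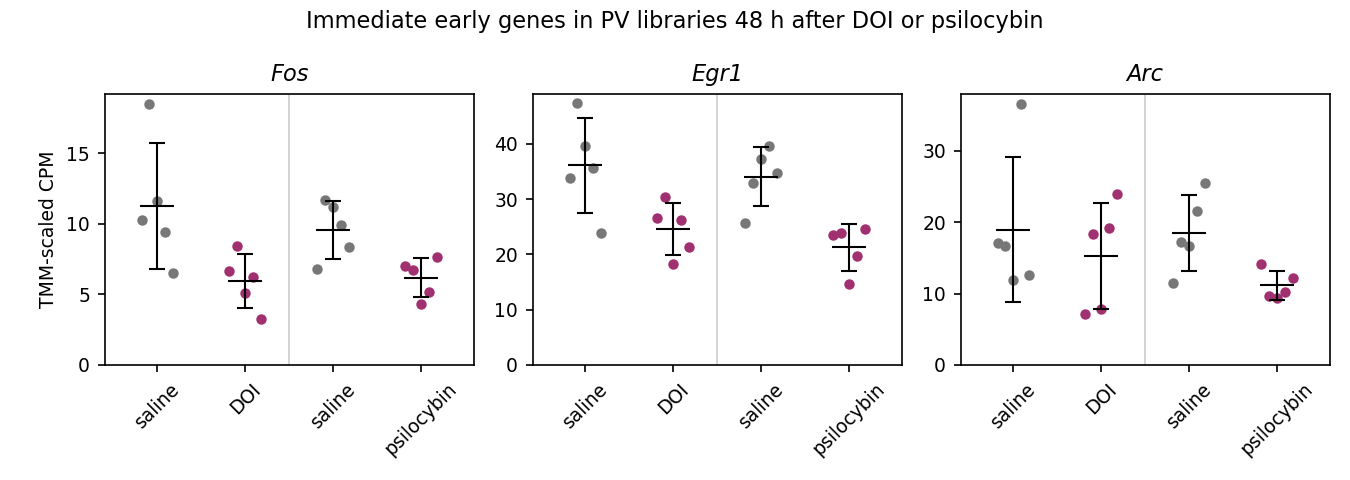
TMM-scaled CPM of Fos, Egr1 and Arc in the PV libraries of the DOI set (left of the grey line) and of the psilocybin set (right) at 48 h, 5 libraries per group; points are libraries, and bars give the mean ± SD. Egr1 averages 24.5 CPM after DOI against 36.1 after saline and 21.3 after psilocybin against 34.1 after its own saline, and none of the 3 genes passed over all genes.

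Differences of the DOI effect between times were called for 0 genes in each line by edgeR, with 875 (Rbp4, 935 by chance), 1390 (Cux2ERT, 929 by chance) and 954 (PV, 941 by chance) at an unadjusted p under 0.05. With no filter on low counts the counts were about 1.0e+02, about 1.1e+02 and 285. Fold changes of 48 h and 1 month after DOI correlated across genes of at least 10 CPM at Pearson r = 0.41 in PV, and those of 48 h and 1 week at r = -0.39 in Cux2ERT, genes not being independent replicates. The other 7 pairs of times within a line lay between -0.227 and 0.177. Over all genes the 9 values lay between -0.068 and 0.036. The effect of DOI differed between lines for 1 gene at 48 h, 3 at 1 week and 3 at 1 month. Ptpru, a receptor tyrosine phosphatase gene, was the only one of these with a mean above 2 CPM, and its log2 fold change at 1 week was 0.45 ± 0.15 in Rbp4, 0.01 ± 0.12 in Cux2ERT and -1.01 ± 0.26 in PV (edgeR adjusted p = 0.00784 for the difference). Leaving out 1 replicate number from every group moved these counts to between 0 and 6 at 48 h, 0 and 31 at 1 week, and 0 and 7 at 1 month.

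The compounds were compared at 48 h and 2 mg/kg each, which is not known to be an equally effective dose. EdgeR called no gene whose response differed between psilocybin and DOI, each set against its own saline group. The counts were 0 of 18253 genes in Rbp4 (378 at an unadjusted p under 0.05 against 913 by chance), 0 of 18700 in Cux2ERT (701 against 935) and 0 of 17528 in PV (991 against 876). With no filter on low counts they were 0, 5 and 22. In Rbp4 the difference of log2 fold changes, psilocybin minus DOI, was 0.06 for Htr2a (95% interval -0.26 to 0.37), -0.32 for Fos (-1.26 to 0.62), -0.50 for Arc (-1.37 to 0.37) and -0.29 for Egr1 (-0.86 to 0.29). In Cux2ERT it was 0.15 for Htr2a (-0.29 to 0.59), 0.11 for Fos (-0.45 to 0.67), -0.09 for Arc (-0.71 to 0.54) and 0.02 for Egr1 (-0.25 to 0.30). In PV it was -0.25 for Htr2a (-0.69 to 0.18), 0.22 for Fos (-0.53 to 0.96), -0.30 for Arc (-1.18 to 0.58) and -0.14 for Egr1 (-0.65 to 0.36). Over the lines, Bdnf and Ntrk2 differed by -0.15 to 0.31. The fits of both sets share 1 sex term, so that these differences are not those between the effects of the separate fits. In Cux2ERT the latter give the other sign for Fos and Egr1. The interval of each of the 6 genes spanned 0 in every line, which does not show that the compounds act alike. For genes of at least 10 CPM the interval reached a median of 0.196 to either side in Rbp4, 0.193 in Cux2ERT and 0.248 in PV. Across such genes the fold changes of DOI and psilocybin correlated at Pearson r = -0.16 in Rbp4, 0.135 in Cux2ERT and -0.183 in PV. Over all genes these values were -0.036, 0.028 and -0.027. The sets also differed in batch and sequencer.

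Lists of serotonin receptors and transport, neurotrophin signalling, dendritic spine actin cytoskeleton and core clock genes were called by camera in none of the 12 drug comparisons. Their smallest camera adjusted p were 0.0586, 0.0944, 0.0666 and 0.104. Adjusted over the list alone, Map1b and Ppp1r9a passed in Rbp4 and Actg1 in PV for spine actin, all 1 month after DOI. Eef2k and Rptor passed in PV at 1 month for neurotrophin signalling, and no serotonin gene did. Of the clock genes, Hlf and Rorb passed in Cux2ERT at 48 h, Bhlhe41 in Cux2ERT at 1 week and Dbp in PV at 1 month. Presynaptic release genes were called once, lower in Rbp4 48 h after DOI for 23 of 30 (median -0.03, adjusted p = 0.00513, and 0.720 with an estimated correlation). Glucocorticoid-responsive genes were lower in Rbp4 after psilocybin (12 of 17, median -0.05, adjusted p = 0.0191) and in PV 1 week after DOI (13 of 17, median -0.18, adjusted p = 0.0299), at 0.642 and 0.720 with an estimated correlation. The first call was lost without psilocybin replicate 2 or 5 or saline replicate 1 or 4 (0.0617 to 0.149), and the latter without DOI replicate 3 or 5 or saline replicate 2, 3 or 4 (0.0501 to 0.387). Presynaptic genes were not called without DOI replicate 1 or saline replicate 4 (0.877 and 0.63). Microglia markers were higher in Cux2ERT 1 week after DOI (13 of 20, median 0.42, adjusted p = 0.0145) and lower in PV after psilocybin (15 of 18, median -0.23, adjusted p = 0.00305), both 0.720 with an estimated correlation. These calls ended without DOI replicate 2 or 3 or saline replicate 5 (0.0512 to 0.0834) and without saline replicate 3 (0.0576). In Rbp4 48 h after DOI, layer 2/3 markers were higher (13 of 22, median 0.04, adjusted p = 0.0088) and layer 5 markers lower (19 of 24, median -0.045, adjusted p = 0.00799), at 0.642 and 0.856 with an estimated correlation. Layer 5 markers were not called without DOI replicate 1 (0.6) or saline replicate 4 (0.228, direction turned). In that saline library Cux2 was at 24.2 CPM (not scaled by TMM) against 42.3 to 71.2 in the others. In PV after psilocybin, layer 6 markers (11 of 13, median -0.22, adjusted p = 0.000386) and markers of other interneurons (11 of 18, median -0.14, adjusted p = 0.0349) were lower, at 0.642 and 0.720 with an estimated correlation. The latter call held in 2 of 10 runs with 1 library left out, those without psilocybin replicate 4 or saline replicate 1. Over all 12 drug comparisons 96 of 384 list tests were called, 40 higher and 56 lower, and 29 of the 96 held in every run with 1 library left out. None held with an estimated correlation, where the smallest adjusted p was 0.231, and fry called 0 for a move in one direction. For change in either direction fry called precursor (adjusted p = 0.00173), pan-excitatory (0.00257) and oligodendrocyte markers (0.026) in PV after psilocybin. It also called spine actin in Rbp4 1 month after DOI (0.0492) and layer 5 markers in Cux2ERT at 1 week (0.026), which camera did not call (0.453 and 0.646).

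The mean transcript length per gene, which moves when a gene's mix of isoforms moves, was tested to address splicing. In Rbp4 at 1 week after DOI 1 gene was called: Kiss1r, the kisspeptin receptor gene, averaged 4330 ± 524 bp against 3228 ± 176 in saline (log2 difference 0.41 ± 0.06, limma adjusted p = 0.0146, n = 5 and 5). Within b1 the means were 4699 against 3104 bp, and within b2 3777 against 3416. The adjusted p was 0.0109 for effective length and 0.247 with a replicate block, and 0.0805, 0.0864 and 0.0976 without DOI replicate 1, 2 or 3 and 0.0965 without saline replicate 2. The count of called genes was 2 with that block, 0 without any 1 of these 4 libraries, 9 and 3 without DOI replicate 4 or 5, and 3, 2 and 5 without saline replicate 1, 3 or 5.

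At 1 month 4 genes were longer in Rbp4 after DOI by the same limma test: the kinesin gene Kif1b (10045 ± 27 against 9938 ± 25 bp, 0.02 ± 0.00, adjusted p = 0.00435), and Iba57 (3914 ± 159 against 3230 ± 289, 0.28 ± 0.05, 0.0297), Impact (3745 ± 64 against 3665 ± 57, 0.03 ± 0.01, 0.0297) and Gramd4 (4167 ± 6 against 4134 ± 21, 0.01 ± 0.00, 0.0488). After psilocybin in Cux2ERT Zfp114 was longer (3079 ± 35 against 2994 ± 6 bp, adjusted p = 0.0244) and Jam3, a junctional adhesion molecule gene (1869 ± 69 against 1970 ± 0), and Gm16973 (2143 ± 16 against 2171 ± 0) were shorter (both 0.0244, n = 4 and 4). These calls too rest on 3 and 4 libraries. In psilocybin replicate 4 Jam3 was at 1970 bp, as in saline, Gm16973 at 2167 and Zfp114 at 3028. In Rbp4 at 1 month the difference had the same direction within b1 and b2 for all 4, with Iba57 at 4020 against 3182 bp in b1 and 3756 against 3303 in b2, and Kif1b at 10055 against 9934 and 10031 against 9943. The count of 4 was 0 for effective length, where Kif1b had an adjusted p of 0.0835. With a replicate block or without the doubted libraries it was 2, with Kif1b at 0.0423 and 0.0146 and the other 3 genes not called (0.176 and 0.0834). It was 13, 2, 1 and 1 without DOI replicate 1, 2, 3 or 5, and 2 and 1 without saline replicate 1 or 3. With 1 library left out at a time, Kif1b had an adjusted p of at most 0.0424. Iba57 and Impact (both up to 0.12) and Gramd4 (up to 0.297) all missed 0.05 without DOI replicate 2, 3 or 5 or saline replicate 1 or 3. Iba57 also missed it without saline replicate 5 (0.0688), and Impact without DOI replicate 4 (0.103) or saline replicate 2 or 4 (0.0669 and 0.0741). Gramd4 missed it without DOI replicate 1 (0.0547) or saline replicate 2 or 5 (0.0891 and 0.0521), and with genes of at least 20 counts included (0.0649). In Cux2ERT the count of 3 was 0 for effective length, with a replicate block, without the doubted libraries, without psilocybin replicate 2 or 3, and without any 1 of saline replicates 1 to 4. Gm16973 had an adjusted p of 0.152 without psilocybin replicate 1. In the other 9 drug comparisons limma called 0 genes. Genes at an unadjusted p under 0.05 numbered 16 in Rbp4 at 48 h (495 by chance) and 372, 355 and 558 in Cux2ERT at 48 h, 1 week and 1 month (490 by chance). They numbered 441, 532 and 361 in PV at these times (475 by chance), and after psilocybin 324 in Rbp4 (494 by chance) and 507 in PV (470 by chance). The count of 0 in PV became 1 and 2 at 48 h without DOI or saline replicate 5, 1 at 1 week without DOI replicate 5, 1 at 1 month without DOI replicate 2, and 2 after psilocybin without saline replicate 3.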

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

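The tests of the PV library without Xist, and for Rbp4 at 48 h the fits without b1, of its 2 groups alone and with a replicate block as tests of the shortfall, were chosen only after the data were seen.

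Immediate early genes were lower in PV libraries 48 h after psilocybin, by a list median of -0.117. In the same libraries the score of excitatory markers differed by -0.26 (two-sided exact permutation p = 0.0159) and that of all glial and vascular markers by -0.20 (0.183). With the glial score as a covariate the median was -0.139 and Egr1 was at -0.57 ± 0.18 (SE) against -0.62 ± 0.15 without it. Fos was at -0.53 ± 0.21 against -0.50 ± 0.18 and Arc at -0.535 ± 0.22 against -0.68 ± 0.20. The glial score pools vascular (0.208) with oligodendrocyte, astrocyte and microglia markers (-0.361, -0.208 and -0.429), so it cannot test carry-over of RNA from glia. With the pan-excitatory score the median was -0.112, Egr1 was at -0.13 ± 0.37, Fos at -0.445 ± 0.465 and Arc at 0.68 ± 0.34. That score itself differed between the groups and the errors widened, so carry-over from excitatory neurons and a change inside PV neurons cannot be told apart. In saline of the psilocybin set Arc averaged 18.43 CPM in PV against 387.2 in Rbp4, Egr1 34.06 against 561.9 and Fos 9.573 against 72.06. With Slc17a7 at 52.21 against 1207 in the DOI set, carry-over could make up most of Arc and Egr1 in PV, but less of Fos. An effect of psilocybin on PV neurons stays open. The unequal sexes do not account for the median, since with sex in the fit it compared males alone (5 psilocybin, 3 saline).

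PV saline 48 h replicate 1, labelled female, held 0 counts of Xist, the RNA that silences an X chromosome. Its Y-linked genes stood at 0.00745 of the male median, which argues against a male under a female label. Too few reads are excluded as well, since 3 counts would give 0.0333 CPM and the other PV libraries from females had 6.65 to 123 CPM. X-linked genes that escape silencing stood at a median of 0.733 of the female libraries and 1.03 of the male ones, with 2 genes below every female library, so that a single X chromosome is a candidate explanation. No explanation by a group of the design was tested.

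Rbp4 at 48 h after DOI had 12 genes at an unadjusted p under 0.05 where chance gives 935. Of 70 splits of these libraries, 5 gave as few, with a median of 77 among the others and a highest of 921. Without batch b1 the number was about 1.1e+02, with the 2 groups fitted alone 226, with a replicate block 40 (same-numbered libraries correlated at a mean of 0.412), and without saline replicate 2, the library with low Y-linked genes, 17. All of these numbers stayed below chance, so that a spread set too wide by b1, by the other times or by differences shared within replicate numbers could account for part of the shortfall, and how much cannot be told apart here. No biological explanation was tested.

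The remaining libraries stood far from the others of their group, by the gap to the nearest library divided by the range of the group. This held for 19 of 336 combinations of a group and a measure, and chance gives about 1 in 20. Cux2ERT saline 1 week replicate 5 had a total count of 122.3 M against a median of 89.9 M in the others (ratio 0.891). Cux2ERT DOI 1 month replicate 5 had a glial score of 1.04 against 0.503 (0.868). Cux2ERT saline replicate 1 of the psilocybin set had 17140 genes with at least 10 counts against 18020 (0.873). In Rbp4 saline at 48 h, Rtn4 was at 557.5 CPM against 515.1 in replicate 2 (0.781), Exosc9 at 25.6 against 41.3 in replicate 5 (0.820) and Fos at 45.2 against 74.2 in replicate 3 (0.740). Htr2a was at 7.998 CPM against 12.3 in Rbp4 saline 1 week replicate 3 (0.742), and Tpp2 at 43.5 against 53.8 in Rbp4 saline 1 month replicate 2 (0.802). In Cux2ERT at 48 h, Htr2a was at 14.8 against 9.06 in saline replicate 4 (0.754), Ntrk2 at 260.4 against 213.5 in DOI replicate 3 (0.720), and Egr1 at 723 against 660.2 in DOI replicate 2 (0.730) and at 815.6 against 665.8 in saline replicate 2 (0.817). In Cux2ERT saline at 1 month, Abhd8 was at 362.7 against 338 in replicate 1 (0.832) and Fos at 115.5 against 41.7 in replicate 3 (0.813). Arc was at 36.5 CPM against 14.6 in PV saline 48 h replicate 4 (0.789). In the psilocybin set, Ttr was at 9.30 against 0.101 in Rbp4 saline replicate 1 (0.783), Bdnf at 25.98 against 31.6 in Rbp4 psilocybin replicate 2 (0.768), Bmp3 at 16.9 against 13.8 in Cux2ERT saline replicate 4 (0.858), and Six3 at 28.6 against 0.291 in PV saline replicate 5 (0.983).

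The effect of DOI differed between lines by an interaction term for 7 genes. Ptpru at 1 week (edgeR adjusted p = 0.00784) was at 0.45 in Rbp4, 0.01 in Cux2ERT and -1.01 in PV. The other genes had means of at most 1.41 CPM, and their fitted fold changes are not given. These were Bcl6b at 48 h (0.0164), Gm34871 (0.00784) and Gm36746 (0.00379) at 1 week, and Vsig10 (0.0188), Gm46110 (0.0395) and Gm52238 (0.0234) at 1 month. Over splits of the labels, 11 of 23 gave as many genes at 48 h (1 real, highest other 4). At 1 week 20 did (3 and 386) and at 1 month 17 (3 and 21), so that chance cannot be excluded at any time. The split with 386 genes points to a structure of the samples, which was not examined.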

How the results depend on the processing

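The surrogate variable, the 2-group fit, Rbp4 without b1, saline lines within b2 and removal of doubted libraries were chosen after the data were seen. Of 343 values of 48 results under another setting, 257 kept their side of the threshold and lay within 1.5 times, and 86 did not. Causes not named below were not tested.

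With no filter on low counts, edgeR called 14, 80 and 124 genes in Rbp4 at 48 h, 1 week and 1 month after DOI, 2, 8 and 52 in Cux2ERT and 140, 312 and about 1.1e+02 in PV, and after psilocybin 46 in Rbp4 and 41 in PV. Differences between times numbered about 1.0e+02 (Rbp4), about 1.1e+02 (Cux2ERT) and 285 (PV), between lines 4, 48 and 11, and between compounds 5 in Cux2ERT and 22 in PV. DESeq2 called 182 and 125 genes in Rbp4 at 1 week and 1 month, 3 and 2 in Cux2ERT at these times, 19, 3 and 7 in PV at 48 h, 1 week and 1 month, and after psilocybin 2 in Cux2ERT and 21 in PV. Voom called 1 in PV at 1 month. With all lines in 1 fit the counts were 85 and 46 in Rbp4 at 1 week and 1 month, 54, 197 and 9 in PV, and 14 in PV after psilocybin. DESeq2 size factors gave 1 gene in Cux2ERT at 1 month, 10 between lines at 1 week and 2 lists in PV at 1 month. Within b2 alone 145 genes were called in Cux2ERT at 1 month and within b3 alone 3. A surrogate variable gave 1 in Cux2ERT at 1 month and 7 in PV after psilocybin, and the fit of only the 2 groups gave 1 in Cux2ERT at 1 week. Without a sex or batch term 1 gene differed between lines at 1 week and 1 at 1 month. Without the doubted libraries the counts were 0 and 7 between lines at 48 h and 1 month, 1 between times in Cux2ERT, 3 in PV after psilocybin, 8 and 2 lists in PV at 48 h and 1 month, and for transcript length 2 in Rbp4 at 1 month and 0 in Cux2ERT after psilocybin. With an estimated correlation or fry's test of 1 direction 0 lists were called throughout. A glial score gave 4 lists in Cux2ERT at 1 week and 4 in Rbp4 after psilocybin. Effective length called 0 genes in Rbp4 at 1 month and 0 in Cux2ERT after psilocybin.

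Same-numbered pairs all correlated over 0.1 only in Rbp4 at 1 week. In Rbp4 at 48 h the lowest was 0.099 and the mean 0.412 (0.388 after removal of sex and batch, against -0.095 between other numbers). With a replicate block the lists numbered 7 in PV at 48 h and 4 at 1 month, and the genes called for transcript length 2 in Rbp4 at 1 month, 2 in Rbp4 at 1 week and 0 in Cux2ERT after psilocybin. The block moved no other count of calls by over 1.5 times. A library correlated best with its own number in 4 of 5 pairs in Rbp4 at 48 h and in PV at 1 month, and in 1 to 3 pairs elsewhere, a hint from the data and not from the design.

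Leaving out each library in turn gave 0 called genes throughout in Rbp4 at 48 h and 1 week, in Cux2ERT at 48 h and 1 week, in PV at 48 h and 1 month, and after psilocybin in Rbp4 and Cux2ERT. The range was 0 to 13 in Rbp4 at 1 month, 0 to 6 in Cux2ERT at 1 month, 0 to 69 in PV at 1 week and 0 to 22 in PV after psilocybin. Called lists ranged over 7 to 17, 0 to 3 and 5 to 8 in Rbp4, 7 to 12, 6 to 10 and 4 to 12 in Cux2ERT, 3 to 7, 6 to 12 and 1 to 5 in PV, and 5 to 15, 6 to 9 and 10 to 14 after psilocybin in Rbp4, Cux2ERT and PV. Transcript length gave 0 to 9 in Rbp4 at 1 week, 1 to 13 at 1 month, 0 to 2, 0 to 1 and 0 to 1 in PV, 0 to 3 and 0 to 2 after psilocybin in Cux2ERT and PV, and 0 elsewhere. The other comparisons were run without 1 replicate number in all groups at once. Differences between times and compounds then stayed at 0 genes, those between lines ranged over 0 to 6, 0 to 31 and 0 to 7 at 48 h, 1 week and 1 month, and saline lines gave 4312 to 6005 (Rbp4 against Cux2ERT), 10555 to 12381 (Rbp4 against PV) and 12366 to 12628 (Cux2ERT against PV).

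Without 1 saline library, 5 called lists turned direction and were not called in the other. These were immediate early genes and layer 5 markers in Rbp4 and ribosomal proteins in PV 48 h after DOI. In Rbp4 after psilocybin they were immediate early genes and, without saline replicate 3, oxidative phosphorylation (adjusted p = 0.891). Of 2893 values of named genes under other settings, 171 had another sign and 92 passed the threshold.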

Other observations

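The comparison of transcript length between saline lines was chosen only after the data were seen, and no test of the splits was.

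Transcript length separated the Cre lines in saline. The protein kinase C gene Prkcb averaged 7918 ± 186 bp (SD) in Rbp4, 8173 ± 147 in Cux2ERT and 3458 ± 138 in PV (log2 difference to PV 1.19 and 1.23, limma adjusted p = 1.94e-33 and 6.02e-36, n = 15 per line). Amph, which encodes amphiphysin, averaged 3308 ± 15 and 3382 ± 13 bp in these lines against 4174 ± 53 in PV. The potassium channel gene Kcnc1 averaged 6423 ± 174 bp in Rbp4 and 5308 ± 97 in Cux2ERT (log2 difference 0.26, adjusted p = 2.22e-19). Of 9954 genes, 188 were called between Rbp4 and Cux2ERT, 1962 between Rbp4 and PV and 2088 between Cux2ERT and PV.

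Labels were split anew within each comparison, and the fits repeated. For called genes the real count was 0 in every drug comparison. All splits (70 after DOI, 100 after psilocybin, there 35 in Cux2ERT) were as large by necessity, which says nothing about chance. The highest other counts after DOI were 0, 11 and 456 in Rbp4, 2, 1 and 2535 in Cux2ERT and 2, 121 and 1 in PV at 48 h, 1 week and 1 month, and after psilocybin 2191, 3 and 34 in Rbp4, Cux2ERT and PV. Differences between times and compounds also had 0 real genes, which decides nothing. Their highest others in these lines were 2, 860 and 1 (times) and 1230, 62 and 3 (compounds). Of genes at an unadjusted p under 0.05, at least 6 of 70 splits gave as many after DOI, 41 of 100 and 33 of 35 after psilocybin. In Rbp4 all 70 did at 1 week (1436 real, 2644 the highest other) and 29 at 1 month (1604 real, 3210 the highest other). Chance cannot be excluded. Splits that called many more genes than the real one point to a structure of the samples, which was not examined.

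For lists, 5 of 70 splits called as many as the real 15 in Rbp4 48 h after DOI (highest other 16), 69 as many as 1 at 1 week (12) and 54 as many as 6 at 1 month (14). In Cux2ERT 26 splits called as many as 11 (16), 29 as many as 8 (14) and 56 as many as 6 (17), and in PV 55 as many as 4 (14), 29 as many as 9 (13) and 70 as many as 1 (11). After psilocybin, 14 of 35 called as many as 9 in Cux2ERT (14) and 19 of 100 as many as 12 in PV (15). Chance cannot be excluded for any of these. In Rbp4 after psilocybin 4 of 100 called as many as 14 (15, 8). That share excludes chance only if taken alone, not over all 12 drug comparisons, and 0 of the 14 lists held with an estimated correlation. The count was 5 without saline replicate 3.

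For transcript length, 44 of 70 splits called as many genes as the real 1 in Rbp4 at 1 week (highest other 16) and 8 as many as 4 at 1 month (14), so that chance cannot be excluded. In Cux2ERT after psilocybin 1 of 35 splits, the real one, called 3 genes (highest other 1). That share excludes chance only if taken alone, not over all 12 drug comparisons. The count was 0 for effective length (adjusted p at least 0.192), with a replicate block, and without any 1 saline library. Elsewhere the real count was 0, which decides nothing, and the highest others were 1 in Rbp4 at 48 h, 1, 0 and 281 in Cux2ERT, 1 at each time in PV, and 32 and 2 after psilocybin in Rbp4 and PV. The split with 281 genes points to a structure of the samples. For the saline lines 1 of 40 splits, the real one, was as large in each pair. Its counts were 6280, 12420 and 13176 genes, the highest others 5963, 5453 and 952. At an unadjusted p under 0.05 another split gave 8675 genes for Rbp4 against Cux2ERT, the real one 7712 (2 of 40 as large). As labels were shuffled over all lines, a split of a pair can hold another line and decides nothing on chance.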
